A study of Homo sapiens with 12 samples.

How the data were processed

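Gene expression was measured on 12 Affymetrix GeneChip Human Gene 2.0 ST arrays, 1 for each combination of 3 gastric cancer cell lines (AGS, MKN1 and SNU601) and 4 treatments (DMSO, Rhosin, JK136 and JK139). Per the labels, the deposited values are log2 signals from robust multi-array average (RMA) processing, which corrects background, brings the arrays to 1 distribution by quantile normalization and summarises the probes of each transcript cluster. The submitters' processing notes name Affymetrix Expression Console and RMA, and the versions were not given in the sources used here. The deposited table held 53617 transcript clusters with values between 0.286 and 13.0 on the log2 scale. Array medians over all clusters lay between 4.14 and 4.20. The doses and the times of exposure are not stated in the labels used here, and the number of arrays limits the precision of every value.

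A gene symbol was available here for 16098 clusters (30.0%), and the other 37519 clusters entered no comparison of genes. Each of the 14884 symbols was represented by its cluster with the highest mean over the 12 arrays, and genes whose mean lay below the 40th percentile (4.61 on the log2 scale) were left out, which left 8930 genes. The annotation release was not stated in the sources used here. ROCK1 and ROCK2, kinases activated by RHOA, were not analysed here because no cluster carried their symbols.

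Differences were tested with limma 3.58.1 in R 4.3.3, with treatment and cell line as fixed terms over all 12 arrays, which left 6 residual degrees of freedom. Because each line had 1 array per treatment, the spread behind each p-value is the spread between lines in their differences, not between cultures of 1 line. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and an adjusted p under 0.05 was called. A difference of responses between lines was tested with limma's F test on the interaction of line with treatment by any compound, which takes the spread between compounds as its error.

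For each of 35 gene lists, those with at least 5 tested genes (27 lists) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The results of 4 of these lists are not reported here, and counts of lists leave them out. Camera with an estimated correlation and fry were run as alternatives. Within a list, counts of genes are also given adjusted over the list alone. As a rule without a p-value, genes that moved at least 1.5-fold the same way in all 3 lines were counted, and the count was repeated after the labels of compound and DMSO were exchanged in 1 line at a time. Correlations between responses are across genes, which are not independent replicates, and were set beside values simulated with shared DMSO arrays and no effect. Responses within 1 line are given as values, since a line has 1 array per treatment.

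The comparisons, the tests, the gene lists, the filter, the thresholds, most alternatives and the rule for named genes were chosen before the data were examined. The minimum of 5 genes per list and 4 further alternatives were chosen afterwards. The rule named the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold. In treatment comparisons it asked for 1 direction in all 3 lines, and it filled up with genes of smallest p and at least 1.5-fold change, which are given as not past the threshold. It also named RHOA, RHOB and RHOC, up to 4 genes of each list, and for each line the 5 strongest rises and falls common to the 3 compounds.

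The model was tested on simulated data with the spread of these arrays. Of changes of 0.5 and 1 on the log2 scale, 44.8% and 97.0% were called for a compound against DMSO, and 73.1% and 97.0% for a comparison of 2 lines. For the interaction, 0% and 34.3% were called, and 89.4% of changes of 2. Simulated changes with a compound against DMSO were the same in all 3 lines, and many genes changed together. These rates therefore do not hold for responses that differ between lines or for few changed genes. The 3 gene lists shifted by 0.3 were called and 0 others were. Simulated genes varied independently, while genes of real lists varied together, such as the replication genes with an estimated correlation of 0.51. The simulation therefore does not show how often camera calls unshifted lists in these data.

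The alternatives covered quantile normalization or median centring of the arrays, other filters, thresholds and priors, array weights, every cluster tested on its own, other ways to treat the block of line or treatment, other list tests, and leaving out each array or line.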

Results

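Transcript levels were measured in 3 established gastric cancer cell lines, AGS, MKN1 and SNU601. Each line was exposed to the solvent DMSO, to Rhosin, a small-molecule inhibitor of the GTPase RhoA, or to 1 of the compounds JK136 and JK139, which the labels give only by code name. Each of the 12 combinations had 1 array, so each line had 4 arrays and each treatment had 3, and the 3 lines served as the replicates of a treatment. Across all 53617 transcript clusters, arrays of 1 line correlated with Pearson's r between 0.978 and 0.988, and arrays of different lines with r between 0.927 and 0.960. Cell line held a median of 82.0% of a gene's sum of squares, treatment 5.30% and the residual 10.9%. These shares are not divided by degrees of freedom, of which treatment had 3 and the residual 6. Per degree of freedom the median share of treatment was no larger than that of the residual. The share of treatment therefore does not show an effect of treatment in a typical gene. Errors of log2 fold changes are standard errors (SE), and levels in a line are means with the SD over its 4 arrays.

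The comparison of Rhosin with DMSO asks which genes respond to this inhibitor. The activity of RhoA was not measured on these arrays. Immediate-early genes, which code for transcription factors and feedback regulators switched on within minutes of a stimulus, were higher after Rhosin in 22 of 24 measured members, with a median log2 fold change of 0.26. Camera called this list and 6 others, and 0 lists were called with an estimated correlation between genes or with fry. The list's median difference was 0.64 in AGS, 0.14 in MKN1 and 0.12 in SNU601. CEACAM5, a cell adhesion glycoprotein of gut epithelium, was higher by 1.11 ± 0.27 and TIPARP, an ADP-ribosyltransferase induced by the aryl hydrocarbon receptor, by 0.74 ± 0.12 (log2, SE, 3 lines). Genes of DNA replication lay lower in 21 of 22 members, with a median of −0.13. With limma, 0 of 8930 genes passed the threshold, 560 had an unadjusted p under 0.05 against 446.5 expected by chance, and the smallest adjusted p was 0.190, so the single genes named for this comparison are given as values.

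CEACAM5 (transcript cluster 16862548, chromosome 19) differed from DMSO by 0.95 in AGS, 1.37 in MKN1 and 1.004 in SNU601, with an adjusted p of 0.532. Its mean level in MKN1 was 3.50, under the 4.61 used as the filter on means, so the difference in that line is not measured well above background. TIPARP (transcript cluster 16947287, chromosome 3) differed by 1.02, 0.73 and 0.47 in the same lines, with an adjusted p of 0.190. ADGRF1, an adhesion G protein-coupled receptor, had a log2 fold change of 0.87, GDF15, a secreted stress cytokine, of 0.66, GRAPL, an adaptor protein, of 0.64, and the microRNA gene MIR152 of 0.61. VIPR1, a receptor for vasoactive intestinal peptide, and PLAC8 each had 0.60, and DHRS3, a retinal reductase, had 0.59. At the low end stood PGAM4, a phosphoglycerate mutase gene, with −0.84, the interferon-induced genes IFIT1 with −0.74 and IFI44 with −0.73, IGFL2, a growth factor-like gene, with −0.69, the protease KLK7 with −0.61 and the antisense transcript SOCS2-AS1 with −0.59. With Rhosin the means of IFIT1 and SOCS2-AS1 lay under 4.61. MT1X, a metal-binding metallothionein, had −0.57 ± 0.10 with an adjusted p of 0.190. All of these differences had 1 sign in the 3 lines, which the naming rule required of genes named for a change of at least 1.5-fold.

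Among the immediate-early genes, FOSL1, an AP-1 subunit, had a log2 fold change of 0.62, JUNB 0.50, IER3 0.43 and FOSB 0.37. EGR1, a zinc finger transcription factor singled out after its values were seen, had 0.63, with 1.67 in AGS, 0.21 in MKN1 and 0.01 in SNU601. Camera called the list at an adjusted p of 2.75e-08, and the adjusted p = 0.436 with an estimated correlation. Of its 24 genes, 0 passed over all genes tested and 0 adjusted over the list alone. The call was lost without the AGS Rhosin array (adjusted p 0.216) and held without all AGS arrays (adjusted p 0.0245, median 0.11).

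Camera called 6 more lists for Rhosin. The G1/S and replication genes had an adjusted p of 0.00582 (adjusted p = 0.678 with an estimated correlation), with TYMS, thymidylate synthase, at −0.22 and MCM10, a replication factor, at −0.21. Mitotic genes lay lower in 19 of 24 members with a median of −0.11 and an adjusted p of 0.0453 (adjusted p = 0.718 with an estimated correlation), including HMMR at −0.27 and CCNB1, cyclin B1, at −0.23. Epithelial markers lay higher in 14 of 20 members with a median of 0.10 and an adjusted p of 0.0374 (adjusted p = 0.338 with an estimated correlation), including KRT8, a keratin, and ESRP1, a splicing factor of epithelial cells, at 0.31 each, and ESRP2 at 0.21. Intestinal markers lay higher in 6 of 7 members with a median of 0.12 and an adjusted p of 0.0453 (adjusted p = 0.338 with an estimated correlation), including CEACAM5 and TFF3, a trefoil peptide, at 0.205. Apoptosis genes lay higher in 10 of 12 members with a median of 0.10 and an adjusted p of 0.0455 (adjusted p = 0.338 with an estimated correlation). They include genes of opposite function, such as the inhibitors of cell death CFLAR at 0.23 and XIAP at 0.19. Targets of the actin-regulated factor SRF lay higher in 8 of 12 members with a median of 0.12 and an adjusted p of 0.0455 (adjusted p = 0.678 with an estimated correlation), including TGFB1I1 at 0.26 and FHL2 at 0.24. In these 6 lists 0 genes passed over all genes tested, and adjusted over the list alone 1 did, CEACAM5.

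Without the AGS arrays none of these 6 lists was called, with adjusted p between 0.0597 and 0.974. The medians of the SRF targets (0.002), replication genes (−0.004) and mitotic genes (−0.03) then lay nearer 0, while those of the epithelial (0.10), apoptosis (0.09) and intestinal lists (0.20) stayed about as large or grew. Without MKN1 the apoptosis genes (adjusted p 0.131, median 0.16) and SRF targets (0.189, median 0.11) were not called. Without SNU601 the mitotic (0.126, median −0.10), apoptosis (0.0588, median 0.15), epithelial (0.0599, median 0.08) and intestinal lists (0.245, median 0.13) were not called. RHOA itself had a log2 fold change of 0.03 ± 0.08 with Rhosin (adjusted p 0.957), RHOB of 0.18 ± 0.19 and RHOC of −0.07 ± 0.13. The other 16 reported lists did not pass, and their medians lay between −0.20 and 0.14. The targets of YAP and TAZ (median 0.05) and the housekeeping genes (−0.08) were among them.

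**Figure D1:**
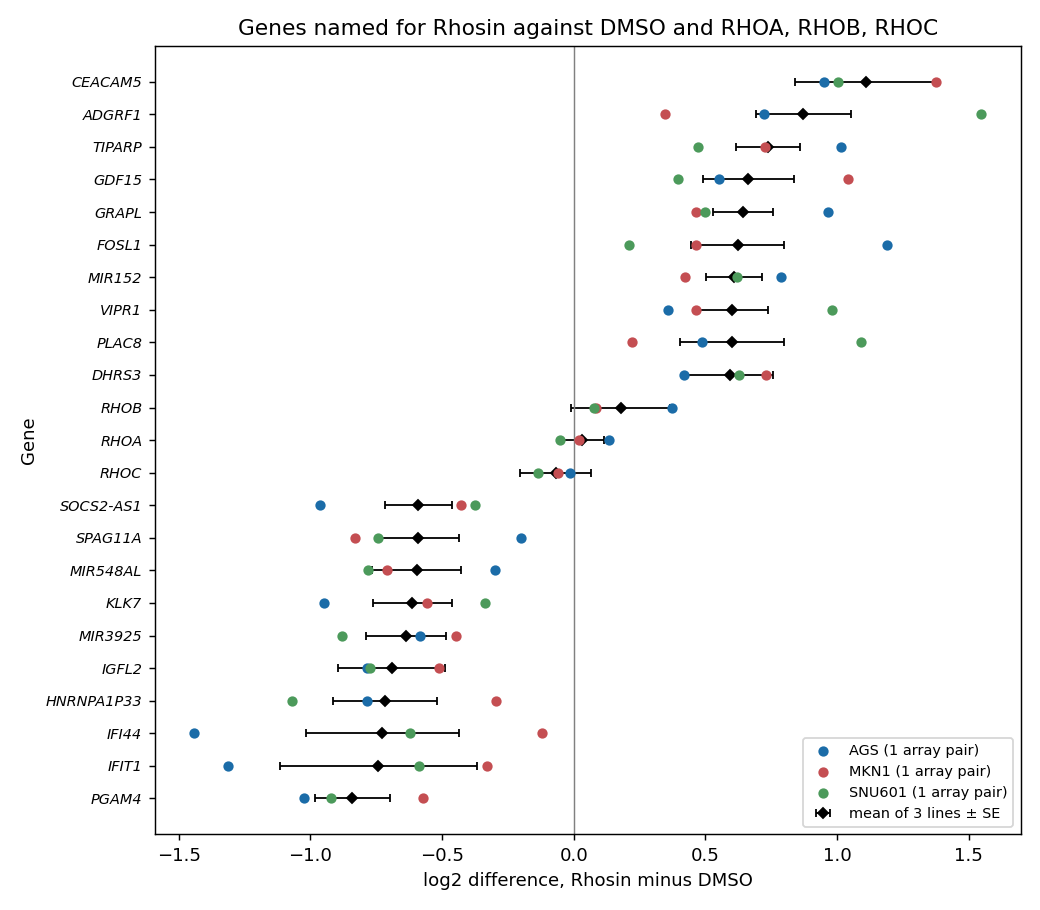
Log2 difference between Rhosin and DMSO (horizontal axis) for genes named for this comparison and for RHOA, RHOB and RHOC (vertical axis), with 1 coloured point per line and a black diamond with SE for the mean of 3 lines. CEACAM5 lies between 0.95 and 1.37 in the 3 lines and RHOA between −0.05 and 0.13.

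The comparison of JK136 with DMSO asks which genes respond to a compound known here only by its code name. Interferon-induced genes lay higher with JK136 in 11 of 14 measured members with a median log2 fold change of 0.24. Camera called this list and 2 other reported lists, and 0 lists were called with an estimated correlation or with fry. The interferon list's median difference was 0.67 in AGS, −0.05 in MKN1 and 0.13 in SNU601. Mitotic genes lay lower in 22 of 24 members with a median of −0.08. With limma, 0 of 8930 genes passed, 469 had an unadjusted p under 0.05 against 446.5 expected by chance, and the smallest adjusted p was 0.801.

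FBXO32, a ubiquitin ligase subunit, had a log2 fold change of 0.81 ± 0.20 with JK136, SAMD9, an interferon-responsive gene, of 0.71 ± 0.32, and GDF15 of 0.70 ± 0.17 (SE, 3 lines). SAMD9 differed by 1.60 in AGS, 0.03 in MKN1 and 0.50 in SNU601, and GDF15 by 0.21, 1.40 and 0.48. The microRNA gene MIR4472-1 had 0.68, AADAC, an esterase, 0.67, STOM, a membrane protein, 0.65, FLG, filaggrin, 0.62, and DKK1, a secreted Wnt antagonist, 0.61. The lower genes included EDAR, a receptor of the TNF family, with −0.63, and TSEN15, a subunit of the tRNA splicing endonuclease, with −0.62. The zinc finger gene ZNF449 and UNC93A had −0.59 each. TIPARP had 0.02 ± 0.12. RHOA had −0.11 ± 0.08 with an adjusted p of 0.936, RHOC had −0.03 ± 0.13, and RHOB had −0.11 ± 0.19, with −0.70 in AGS, 0.15 in MKN1 and 0.22 in SNU601.

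Interferon-induced genes were called at an adjusted p of 0.00290 (adjusted p = 0.594 with an estimated correlation), including XAF1 and MX2 at 0.52 each and the RNA sensor RIGI at 0.48. Heat shock genes, which code for chaperones, lay higher in 8 of 8 members with a median of 0.11 and an adjusted p of 0.0255 (adjusted p = 0.594 with an estimated correlation), including HSPA4L at 0.44 and HSPH1 at 0.20. Mitotic genes were called at an adjusted p of 0.00815 (adjusted p = 0.594 with an estimated correlation), including the kinase AURKB at −0.26, NUSAP1 at −0.20 and the centromere histone CENPA at −0.20. In these 3 lists 0 genes passed over all genes tested or adjusted over the list alone.

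Without AGS the interferon-induced genes (adjusted p 0.343, median 0.08) and the heat shock genes (adjusted p 0.246, median 0.06) were not called. The heat shock genes were not called without MKN1 either (adjusted p 0.169), although their median was then 0.15. The mitotic genes were called without AGS (adjusted p 0.0206, median −0.09) and not without SNU601 (adjusted p 0.632, median −0.06). The other 20 reported lists did not pass, and their medians lay between −0.11 and 0.11.

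For JK139 against DMSO, limma called 0 of 8930 genes, 218 had an unadjusted p under 0.05 against 446.5 expected by chance, and the smallest adjusted p was 0.9999. The zinc finger gene ZNF107 was the sole gene of at least 1.5-fold that the naming rule took for size and direction, with a log2 fold change of 0.60 ± 0.11. TIPARP had 0.02 ± 0.12, and CEACAM5, chosen here after its values were seen, had 0.16 ± 0.27. RHOA had −0.08 ± 0.08, RHOB −0.03 ± 0.19 and RHOC −0.15 ± 0.13. Camera called 0 of the 23 reported lists, as did camera with an estimated correlation and fry, and the list medians lay between −0.10 and 0.08. The smallest adjusted p of a list was 0.277, for the targets of NRF2, the regulator of antioxidant genes.

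For the mean of the 3 compounds against DMSO, limma called 0 genes, with 301 at an unadjusted p under 0.05, and no adjusted p under 0.05. Immediate-early genes lay higher in 19 of 24 members with a median of 0.09 and were called by camera at an adjusted p of 0.00569 (adjusted p = 0.757 with an estimated correlation). FOSL1 had 0.36 and IER3 0.21, and 0 members passed over all genes tested or adjusted over the list alone. The call was lost without the Rhosin array of AGS (adjusted p 0.237), without its DMSO array (adjusted p 0.340) and without AGS (adjusted p 0.107, median 0.07). MT1X had −0.35 ± 0.08, with a negative difference in each line.

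**Figure D2:**
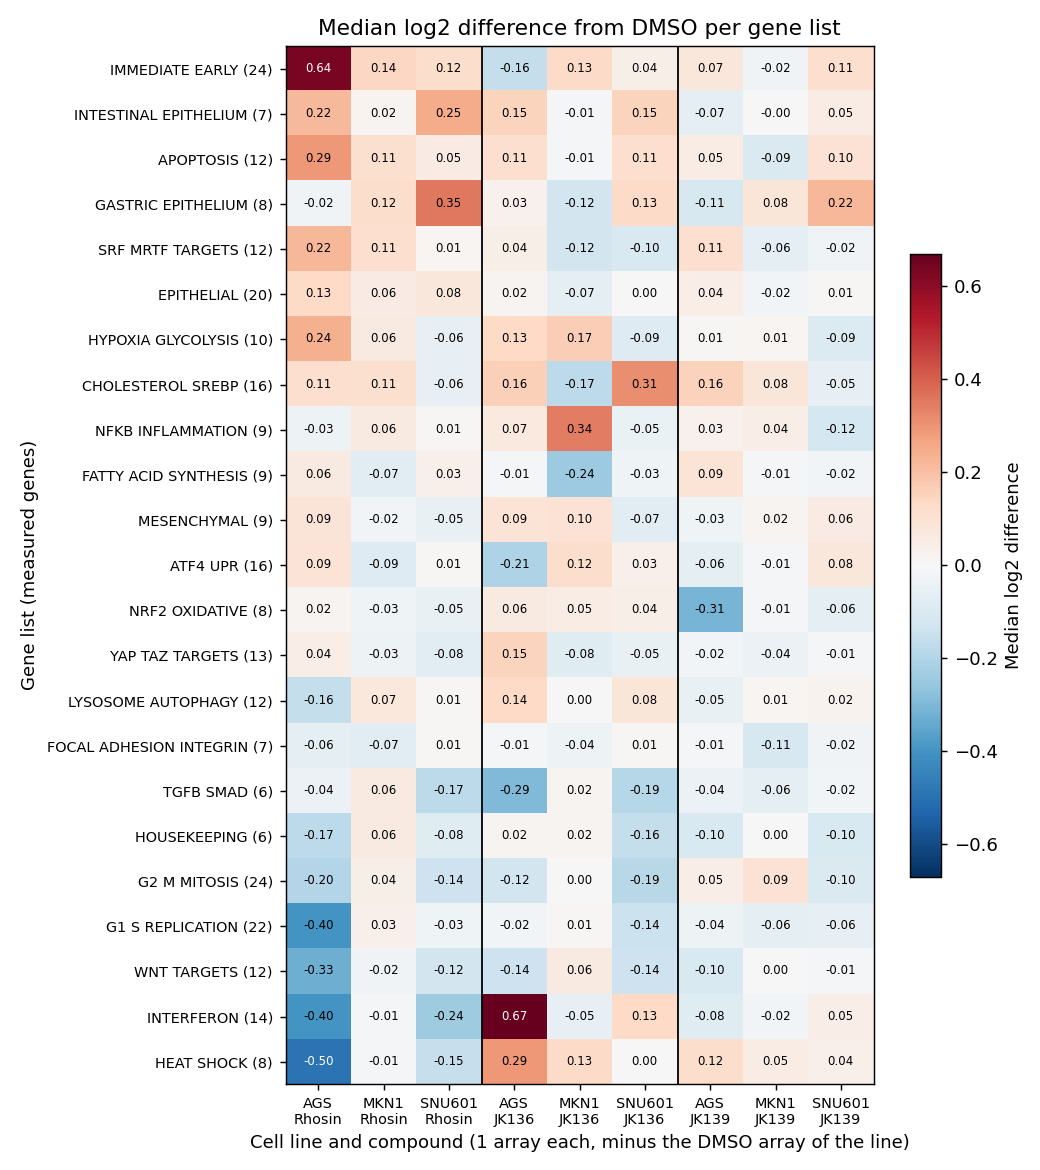
Median log2 difference from the DMSO array of the same line (colour and printed value) for 23 gene lists (vertical axis, with the number of measured genes) in each line and compound (horizontal axis, 1 array each). In AGS the immediate-early genes stood at 0.64 with Rhosin, and the interferon-induced genes stood at 0.67 with JK136.

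The compounds were also compared with each other on the arrays of the same lines; whether their doses and times matched is not stated in the labels. Camera called 6 reported gene lists between JK136 and Rhosin, and 0 lists were called with an estimated correlation or with fry. Immediate-early genes lay lower with JK136 than with Rhosin in 21 of 24 members with a median of −0.24, and targets of SRF in 12 of 12 with a median of −0.15. Interferon-induced genes lay higher with JK136 in 12 of 14 members with a median of 0.49 and heat shock genes in 8 of 8 with 0.34. Limma called 0 of 8930 genes, 812 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0999. The 95% confidence interval of a difference between 2 compounds, not adjusted over genes, reached a median of 0.242 to either side. Differences below about that size stay open for a typical gene, and so do larger ones, since 0 genes passed after adjustment.

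CEACAM5 differed between JK136 and Rhosin by −1.37 ± 0.27, with −2.27 in AGS, −1.26 in MKN1 and −0.58 in SNU601 (adjusted p 0.257). TIPARP differed by −0.72 ± 0.12, with −1.08, −0.65 and −0.42 (adjusted p 0.257). Lower with JK136 were also EGR1 with −1.21, of which AGS gave −2.66, CTH, an enzyme of cysteine synthesis, with −0.92, JUNB with −0.66 and the homeobox gene HOXC13 with −0.59. Higher with JK136 were KITLG, the ligand of the receptor KIT, with 0.67, PHYH, a peroxisomal enzyme, with 0.64, and SAMHD1, a nucleotide hydrolase, with 0.61. MT1X had 0.35 ± 0.10. RHOA differed by −0.14 ± 0.08 (adjusted p 0.624), RHOB by −0.29 ± 0.19 and RHOC by 0.04 ± 0.13.

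The camera adjusted p was 2.49e-05 for the immediate-early genes (adjusted p = 0.492 with an estimated correlation), and 4 of its members passed adjusted over the list alone, EGR1, FOS with −0.70, JUNB and the phosphatase DUSP2 with −0.58. The SRF targets had 0.00449 (adjusted p = 0.384 with an estimated correlation), with FHL2 at −0.24 and ZYX at −0.23. Fatty acid synthesis genes lay lower with JK136 in 8 of 9 members with a median of −0.16 and an adjusted p of 0.00308 (adjusted p = 0.384 with an estimated correlation), and adjusted over the list alone 2 passed, the lipogenic regulator SREBF1 with −0.48 and the desaturase SCD with −0.37. The interferon-induced genes had 3.36e-05 (adjusted p = 0.384 with an estimated correlation), and IFI44 passed adjusted over the list alone with 1.09. Heat shock genes had 9.63e-05 (adjusted p = 0.384 with an estimated correlation), and HSPH1 with 0.48 and HSPB1 with 0.47 passed adjusted over the list alone. Replication genes lay higher with JK136 in 17 of 22 members with a median of 0.13 and an adjusted p of 0.0302 (adjusted p = 0.865 with an estimated correlation), with E2F1 at 0.28 and CCNE2 at 0.28, and 0 members passed adjusted over the list alone. In all 6 lists 0 genes passed over all genes tested.

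Without AGS, of these 6 lists the fatty acid synthesis genes stayed called (adjusted p 0.00255), and the call of that list was lost without MKN1 (adjusted p 0.212, median −0.12), as was that of the SRF targets (adjusted p 0.198, median −0.16). The replication genes had a median of −0.05 without AGS, opposite in sign, and the other 4 lists were not called, with adjusted p between 0.0597 and 0.521. Of these the SRF targets kept a median of −0.14, while the immediate-early genes moved from −0.24 to −0.03, the heat shock genes from 0.34 to 0.11 and the interferon-induced genes from 0.49 to 0.14.

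Between JK139 and Rhosin camera called 4 gene lists, and 0 were called with an estimated correlation or with fry. Immediate-early genes lay lower with JK139 in 22 of 24 members, with a median of −0.23. Heat shock genes lay higher in 7 of 8 members with a median of 0.28, interferon-induced genes in 12 of 14 with 0.20 and mitotic genes in 18 of 24 with 0.10. Limma called 0 of 8930 genes, 663 had an unadjusted p under 0.05, and the smallest adjusted p was 0.358, that of TIPARP, which differed by −0.71 ± 0.12 with −1.08 in AGS, −0.60 in MKN1 and −0.47 in SNU601.

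CEACAM5 differed between JK139 and Rhosin by −0.95 ± 0.27, ADGRF1 by −0.69, the calcium-binding protein gene CALB2 by −0.67, STC2, a secreted glycoprotein, by −0.67 and GDF15 by −0.60. SOX2, a transcription factor of stem cells and stomach epithelium, differed by 0.84, with 1.85 in AGS, and IFI44 by 0.74, the kinase MAP2K6 by 0.72 and the antiviral tetherin gene BST2 by 0.62. RHOA differed by −0.12 ± 0.08 (adjusted p 0.774), RHOB by −0.21 ± 0.19 and RHOC by −0.08 ± 0.13. The camera adjusted p was 9.48e-06 for the immediate-early genes (adjusted p = 0.565 with an estimated correlation), with FOSL1 at −0.53, ATF3 at −0.47 and JUN at −0.45. Heat shock genes had 0.0138 (adjusted p = 0.565 with an estimated correlation), with HSPH1 at 0.39 and CHORDC1 at 0.35. Mitotic genes had 0.0233 (adjusted p = 0.618 with an estimated correlation), with HMMR at 0.38 and CCNB1 at 0.25, and interferon-induced genes had 0.0336 (adjusted p = 0.618 with an estimated correlation). In the 4 lists 0 genes passed over all genes tested or adjusted over the list alone. All 4 calls were lost without AGS, with adjusted p between 0.186 and 0.613, and all 4 without the AGS Rhosin array. Without AGS the medians were −0.11 for the immediate-early, 0.09 for the heat shock, 0.11 for the interferon-induced and 0.02 for the mitotic genes. The interferon call was lost without SNU601 (adjusted p 0.471, median 0.16).

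For JK139 against JK136 camera called 4 reported gene lists, and 0 lists were called with an estimated correlation or with fry. Targets of NRF2 lay lower with JK139 than with JK136 in 7 of 8 members with a median of −0.17 and interferon-induced genes in 12 of 14 with −0.25. Mitotic genes lay higher with JK139 in 21 of 24 members with a median of 0.11, and fatty acid synthesis genes in 6 of 9 with 0.11. Limma called 0 of 8930 genes, 494 had an unadjusted p under 0.05 and the smallest adjusted p was 0.883. DKK1 differed by −0.83 ± 0.28, AADAC by −0.63 ± 0.15 and GDF15 by −0.63 ± 0.17. Each had 1 sign in the 3 lines, which the naming rule required of genes named for their size. RHOA differed by 0.03 ± 0.08, RHOB by 0.08 ± 0.19 and RHOC by −0.12 ± 0.13.

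Mitotic genes were called at an adjusted p of 0.00160 (adjusted p = 0.753 with an estimated correlation), with HMMR at 0.23, the topoisomerase TOP2A at 0.18 and KIF23 at 0.16. The NRF2 targets had 0.00164 (adjusted p = 0.571 with an estimated correlation), with HMOX1, heme oxygenase, at −0.43, of which AGS gave −1.30, and TALDO1 at −0.25. Fatty acid synthesis genes had 0.0273 (adjusted p = 0.571 with an estimated correlation), and SREBF1 with 0.45 and SCD with 0.39 passed adjusted over the list alone. Interferon-induced genes had 0.0393 (adjusted p = 0.790 with an estimated correlation), with IFIT3 at −0.44. Over all genes tested 0 members of the 4 lists passed, and in the mitotic, NRF2 and interferon lists 0 passed adjusted over the list alone. Without AGS the mitotic genes stayed called (adjusted p 0.0109), and the other 3 lists were not, with adjusted p between 0.0610 and 0.992. The fatty acid synthesis genes then had a median of 0.15, the NRF2 targets −0.03 and the interferon-induced genes −0.01. The fatty acid synthesis call was also lost without MKN1 (adjusted p 0.436, median 0.06).

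The size rule asked for at least 1.5-fold the same way in each of the 3 lines. CEACAM5 met it with Rhosin, although its mean level in MKN1 lay under the filter's 4.61, and 0 genes met it with JK139. MIR4472-1 met it with JK136, with differences of 0.71, 0.68 and 0.65 from a mean DMSO level of 4.43, which also lay under 4.61. After labels were exchanged in 1 line, the highest counts were 1, 0 and 0. Within a line, the SD of the differences from DMSO across genes was 0.281 for Rhosin and 0.273 for JK136 in AGS, and it lay between 0.187 and 0.230 in the other 7 combinations.

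Whether the lines responded differently was tested with the interaction of line and treatment. The F test of limma called 0 of 8930 genes, 244 had an unadjusted p under 0.05 and no adjusted p was under 0.05. Camera on these differences called 0 of the reported lists, and the smallest adjusted p was 0.0665, for mitotic genes and for gastric markers in SNU601 against MKN1. The values within a line therefore stand as descriptions of single arrays. The 3 differences of a line share its 1 DMSO array, and the genes were ranked by the smallest of these differences. A rise or fall common to the 3 compounds can thus come from that DMSO array alone. In AGS the collagenase MMP1 was higher than with DMSO by 2.58 with Rhosin, 0.83 with JK136 and 0.90 with JK139, and ANXA2, annexin A2, by 0.59, 0.60 and 0.61. PHC1, a Polycomb protein, was lower in AGS, with −0.84, −0.74 and −0.76. In MKN1 the zinc finger gene ZNF430 stood at 0.70, 0.69 and 1.39 and STRA6, a retinol transporter, at 0.71, 0.58 and 0.61, while LLGL2, a cell polarity gene, stood at −0.88, −1.04 and −0.68. In SNU601 the imprinted gene MEST stood at 0.94, 1.47 and 1.05, FJX1 at 1.06, 0.85 and 0.88 and the protease KLK11 at 0.89, 0.95 and 0.73. On the DMSO arrays of these lines MEST stood at 2.26, FJX1 at 3.28 and ZNF430 at 4.47, under the filter's 4.61, so their differences start near background. The transcription factor KLF7 stood at −1.52, −1.11 and −0.70 in SNU601, where its DMSO level was 4.77, so these falls end under 4.61 and are limited by background.

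Responses of 2 compounds in 1 line share that line's DMSO array, and across genes they correlated with Pearson's r between 0.177 and 0.504 (9 pairs, median 0.457). Arrays simulated with a shared DMSO array and no effect gave r of 0.501. Responses to 1 compound in 2 lines share no array, and their r lay between −0.056 and 0.197 (9 pairs, median −0.0051), with the highest value for Rhosin in AGS and SNU601. Responses to different compounds in different lines had r between −0.128 and 0.0829 (18 pairs).

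Comparisons of the lines average the 4 arrays of a line, which had 4 different treatments. They therefore do not describe untreated cells, and the SD over these arrays also holds differences between treatments. In these comparisons, counts of genes that rose or fell, or were higher or lower, are of genes past the threshold. Counts of members that lay higher or lower are by sign alone. In MKN1 against AGS camera called the lists of epithelial, intestinal and Wnt target genes as lower and the mesenchymal list as higher, and 0 lists were called with an estimated correlation. FN1, fibronectin, stood at 9.59 ± 0.08 in MKN1 and 3.42 ± 0.09 in AGS (log2, SD, n = 4), and VIM, vimentin, at 8.26 ± 0.15 and 4.38 ± 0.08. CTSE, a protease of gastric epithelium, stood at 5.35 ± 0.41 in MKN1 and 12.32 ± 0.07 in AGS. Of 8930 genes, 3153 were higher and 2766 lower in MKN1, and 1446 of these differed at least 2-fold.

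The enzyme CD38 had the highest log2 fold change in MKN1 against AGS, 6.77 ± 0.11, followed by the helicase-like gene HLTF with 6.62, the matrix gene MAMDC2 with 6.29, FN1 with 6.17, and the secreted proteins EDIL3 with 5.90, LUM with 5.86 and IGFBP3 with 5.80. At the low end stood the formyl peptide receptor FPR3 with −7.25 ± 0.10, LYZ, lysozyme, with −7.09, CTSE with −6.97, and the adhesion molecules CEACAM6 with −6.53 and CEACAM5 with −5.79. In the line with the lower level all of these but CTSE stood under the filter's 4.61, such as CD38 at 3.43 in AGS and FPR3 at 2.88 in MKN1, so the size and order of these differences are limited by background. Mesenchymal genes rose in 7 of 9 members and 1 fell, with a median of 3.29 and a camera adjusted p of 0.00311 (adjusted p = 0.105 with an estimated correlation). They included TNC, tenascin, with 4.62 and the hyaluronan receptor CD44 with 3.72. Epithelial genes fell in 15 of 20 members and rose in 5, with a median of −1.12 and a camera adjusted p of 0.00253 (adjusted p = 0.105 with an estimated correlation). ESRP1 fell by 4.84, the transcription factor GRHL2 by 3.63, the claudin CLDN7 by 3.57 and the adhesion molecule EPCAM by 3.55. TNC in AGS and ESRP1 and GRHL2 in MKN1 lay under 4.61.

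Wnt targets lay lower in 11 of 12 members, 8 of them past the threshold. Their median was −1.64, with a camera adjusted p of 0.00129 (adjusted p = 0.105 with an estimated correlation). They included the stem cell receptor LGR5 with −5.71, the receptor ubiquitin ligase RNF43 with −5.19 and the feedback inhibitors AXIN2 with −3.75 and NKD1 with −2.73. Intestinal markers lay lower in 7 of 7 members, 4 of them past the threshold. Their median was −1.14, with a camera adjusted p of 0.00895 (adjusted p = 0.128 with an estimated correlation). They included VIL1, villin, with −3.63 and the homeobox gene CDX2 with −1.14. Over the alternatives the median of the intestinal list ranged from −1.20 to −0.17, the last without a filter. Genes of the ATF4 and unfolded protein responses fell in 13 of 16 members and 2 rose, with a median of −0.90 and a camera adjusted p of 0.00309 (adjusted p = 0.332 with an estimated correlation). In that list XBP1 had −2.17, ATF4 −1.32 and the serine synthesis gene PHGDH 2.29. Fatty acid synthesis genes rose in 6 of 9 members, with a median of 0.73 and a camera adjusted p of 0.0149 (adjusted p = 0.332 with an estimated correlation), with the elongase ELOVL5 at 4.18 and the desaturase FADS1 at 2.03. Mitotic genes rose in 14 of 24 members and 1 fell, with a median of 0.31 and a camera adjusted p of 0.0233 (adjusted p = 0.638 with an estimated correlation), with KIF20A at 1.44 and the kinase PLK1 at 1.07. The counts adjusted over the list alone were the same as those over all genes for these 7 lists. LGR5, RNF43 and VIL1 in MKN1 and PHGDH, ELOVL5 and FADS1 in AGS lay under 4.61, so their differences are limited by background. The mitotic call was lost without the AGS Rhosin array (adjusted p 0.0621) and without the MKN1 Rhosin array (adjusted p 0.0509), and the fatty acid synthesis call was lost with a filter at the 60th percentile (adjusted p 0.169).

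In SNU601 against AGS camera called the gastric and cholesterol synthesis lists as higher, and 0 lists were called with an estimated correlation. EPCAM stood at 10.19 ± 0.13 in SNU601 and 10.04 ± 0.06 in AGS, with an adjusted p of 0.265. CLDN18, the claudin of stomach epithelium, stood at 9.52 ± 0.05 in SNU601 and 4.02 ± 0.03 in AGS (log2, SD, n = 4), and the chemokine CXCL5 at 10.42 ± 0.37 and 4.48 ± 0.26. FPR3 stood at 3.02 ± 0.14 in SNU601 and 10.13 ± 0.09 in AGS. Of 8930 genes, 2673 were higher and 2037 lower in SNU601, and 745 of these differed at least 2-fold.

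The highest log2 fold changes of SNU601 against AGS were 5.94 ± 0.13 for CXCL5, 5.50 for CLDN18 and 5.38 for the mucin-like gene MUCL3, followed among others by ANXA5, annexin A5, with 4.91, PIWIL1, a germline Argonaute-family protein, with 4.88 and AGR2, a protein disulfide isomerase of mucus-secreting cells, with 4.61. The lowest were −7.11 ± 0.10 for FPR3, −6.37 for RHOBTB3, an ATPase of vesicle transport, −4.71 for HSPA4L and −4.51 for DIAPH2, a formin, and VTN, vitronectin, had −4.26. In the line with the lower level all of these but VTN stood under the filter's 4.61. Gastric markers rose in 6 of 8 members, with a median of 1.59 and a camera adjusted p of 0.00283 (adjusted p = 0.415 with an estimated correlation), including ANXA10 with 3.79 and the trefoil peptide TFF2 with 2.73, both under 4.61 in AGS. Over the alternatives the median of the gastric list ranged from 0.75, without a filter, to 1.77. Cholesterol synthesis genes lay higher in 16 of 16 members, with a median of 1.15 and a camera adjusted p of 9.34e-06 (adjusted p = 0.452 with an estimated correlation). Of these members, 13 passed the threshold, and 14 did when adjusted over the list alone. They included the sterol sensor INSIG1, at 8.78 ± 0.31 in SNU601 and 5.78 ± 0.26 in AGS, SQLE with 1.62 and NSDHL with 1.56. Replication genes rose in 15 of 22 members and fell in 5, with a median of 0.38 and a camera adjusted p of 0.0350 (adjusted p = 0.617 with an estimated correlation), with GINS2 at 1.535 and MCM3 at 1.12. Mitotic genes lay higher in 23 of 24 members, 15 of them past the threshold. Their median was 0.29, with a camera adjusted p of 0.00227 (adjusted p = 0.499 with an estimated correlation), and TTK stood at 0.95 and AURKB at 0.66.

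Wnt targets fell in 10 of 12 members in SNU601 against AGS and 1 rose, with a median of −0.80 and a camera adjusted p of 0.000594 (adjusted p = 0.306 with an estimated correlation), with PROX1 at −1.97, NKD1 at −1.82, SP5 at −1.50 and AXIN2 at −0.82. Genes of the ATF4 and unfolded protein responses fell in 11 of 16 members and rose in 2, with a median of −0.44 and a camera adjusted p of 0.00851 (adjusted p = 0.461 with an estimated correlation), with ASNS, asparagine synthetase, at −4.07 and the pseudokinase TRIB3 at 2.04. Adjusted over the list alone, the counts of the lists other than cholesterol synthesis were the same as over all genes. PROX1 and ASNS lay under 4.61 in SNU601. The calls of the gastric markers (adjusted p 0.162) and of the replication genes (adjusted p 0.144) were lost with a filter at the 60th percentile, and that of the replication genes also without the Rhosin array of AGS (adjusted p 0.0974) or of SNU601 (adjusted p 0.0853).

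In SNU601 against MKN1 camera called the epithelial and gastric lists as higher, and 0 lists were called with an estimated correlation. CEACAM6 stood at 11.33 ± 0.12 in SNU601 and 2.60 ± 0.35 in MKN1 (log2, SD, n = 4), and CD38 at 3.24 ± 0.09 and 10.20 ± 0.17. Of 8930 genes, 2880 were higher and 2780 lower in SNU601, and 1433 of these differed at least 2-fold. The highest log2 fold changes were 8.72 ± 0.15 for CEACAM6, 8.10 for LYZ, 6.84 for CTSE, 6.18 for CEACAM5, 5.76 for CLDN18, 5.49 for CXCL5 and 5.30 for AGR2. The lowest were −6.96 ± 0.11 for CD38, −6.59 for HLTF and −6.46 for RHOBTB3, and FN1 had −6.09. In the line with the lower level all of these but CTSE and CXCL5 stood under the filter's 4.61.

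Gastric markers rose in 8 of 8 members in SNU601 against MKN1, with a median of 3.06 and a camera adjusted p of 0.000152 (adjusted p = 0.0930 with an estimated correlation), including TFF1 with 4.08 and ANXA10 with 3.63. Over the alternatives that median ranged from 1.75, without a filter, to 4.08, at the 60th percentile. Epithelial genes rose in 15 of 20 members and fell in 4, with a median of 1.22 and a camera adjusted p of 0.000353 (adjusted p = 0.0819 with an estimated correlation), including ESRP1 with 4.75, CLDN7 with 3.97 and EPCAM with 3.70. Intestinal markers rose in 5 of 7, with a median of 0.69 and a camera adjusted p of 0.00486 (adjusted p = 0.0956 with an estimated correlation), including VIL1 with 3.21. Cholesterol synthesis genes rose in 13 of 16 members and fell in 2, with a median of 0.64 and a camera adjusted p of 0.0156 (adjusted p = 0.774 with an estimated correlation), including SQLE with 1.501 and SREBF2, the regulator of the pathway, with 1.20. Mesenchymal genes fell in 8 of 9 members and 1 rose, with a median of −2.53 and a camera adjusted p of 0.000611 (adjusted p = 0.0819 with an estimated correlation), with TNC at −4.79, VIM at −4.10 and the transcription factor SNAI2 at −3.04. Targets of YAP and TAZ fell in 10 of 13 members and rose in 2, with a median of −1.05 and a camera adjusted p of 0.00303 (adjusted p = 0.120 with an estimated correlation), with IGFBP3 at −5.76, FJX1 at −3.41, CRIM1 at −2.84 and the matricellular protein CCN2 at −2.23. Of the genes named from these lists, TFF1, ANXA10, ESRP1 and VIL1 in MKN1 and TNC, VIM, SNAI2, IGFBP3 and FJX1 in SNU601 lay under 4.61, so their differences are limited by background. Counts adjusted over the list alone were the same as those over all genes for these 6 lists. With a filter at the 60th percentile the calls of the YAP and TAZ targets (adjusted p 0.0502) and of cholesterol synthesis (adjusted p 0.126) were lost.

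**Figure D3:**
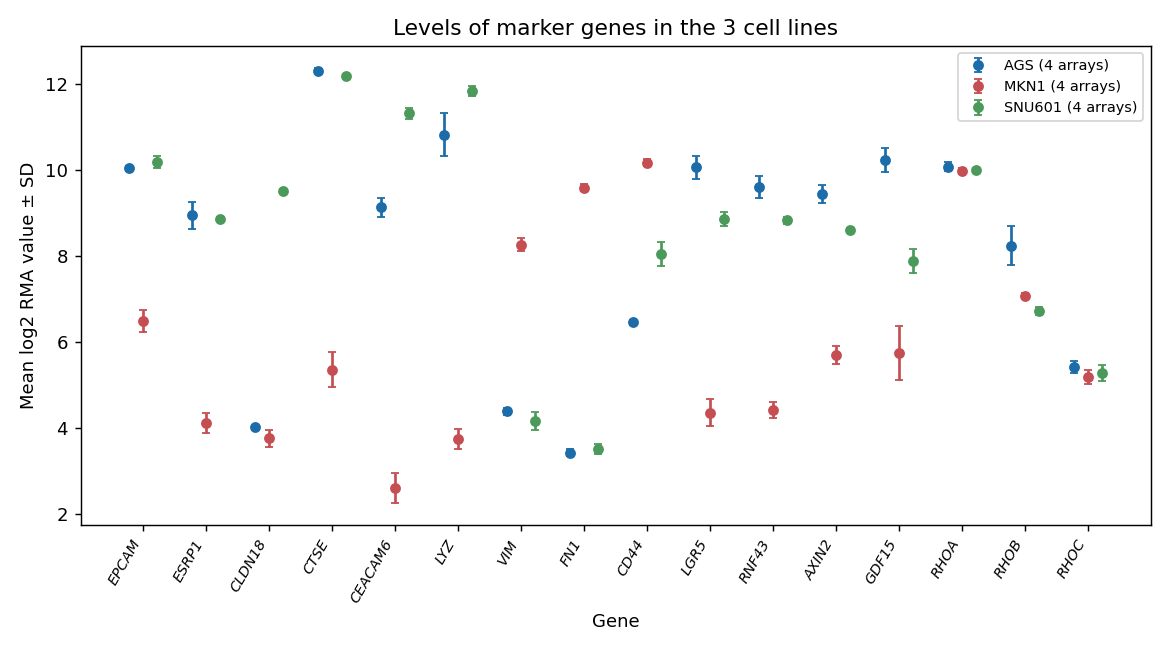
Mean log2 RMA level with SD over 4 arrays (vertical axis) of marker genes and of RHOA, RHOB and RHOC (horizontal axis) in AGS, MKN1 and SNU601. FN1 stood at 9.59 in MKN1 against 3.42 in AGS, CLDN18 at 9.52 in SNU601 against 4.02 in AGS, and RHOA between 9.98 and 10.08 in the 3 lines.

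RHOA (transcript cluster 16954055, chromosome 3) stood at 10.08 ± 0.11 in AGS, 9.98 ± 0.07 in MKN1 and 10.01 ± 0.05 in SNU601 (log2, SD, n = 4), and its adjusted p was 0.226 for MKN1 and 0.426 for SNU601 against AGS. RHOB stood at 8.24 ± 0.45 in AGS, and it fell by 1.16 in MKN1 and by 1.52 in SNU601 (adjusted p 4.9e-05 and 1.03e-05). RHOC stood at 5.42 ± 0.15, 5.17 ± 0.16 and 5.27 ± 0.19, and its difference between MKN1 and AGS was −0.25 with an adjusted p of 0.0808, which became 0.0406 with −0.30 after quantile normalization. LIMK2, a kinase of actin turnover, had −1.50 in MKN1 and the GTPases RHOU and RHOF had −1.27 and 1.11 there, all called. In SNU601 the GTPase RHOQ, under 4.61 there, had −1.59 and profilin, PFN1, had 0.59 against AGS, both called.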

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

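The comparison of single arrays with the others of a line, the other divisions of the arrays and the tests of explanations were chosen only after the results were seen, and the gene and list calls they refer to were planned. For each of 23 gene lists and for RHOA, RHOB and RHOC, the array of a line whose mean level stood farthest from the other 3 was compared with their spread, in 78 groups. Of these, 1 stood apart, and chance flags about 1 in 20 groups, which is 3.9 of 78. In AGS the hypoxia and glycolysis genes stood at 6.34 with Rhosin against 6.02 to 6.05 on the other arrays, with a gap that made up 0.894 of the range. Clusters without a gene symbol here were also tested, 12937 in number. Of these, 6732 differed between MKN1 and AGS, 4748 between SNU601 and AGS and 6256 between SNU601 and MKN1, and 0 in any treatment comparison. Their genes were not analysed here.

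The gene counts between lines were compared with all 35 ways to divide 8 arrays into 2 sets of 4. The real division alone called genes (1 of 35 each: 5919, 4710 and 5660 genes, highest other 0). Every other division mixes the 2 lines, and cell line held a median of 82.0% of a gene's sum of squares. Such a division puts the line difference into the residual, so counts of 0 there do not test the real counts against chance. Among the 8 divisions that part the 2 arrays of every treatment, 1 reached each real count. These divisions are too few for a share under 0.05. List counts of 7, 6 and 6 were reached in 5, 6 and 8 of the 35 divisions (highest others 7, 8 and 6), so chance is not excluded for those numbers of lists. Divisions that exchange 1 array of each line keep part of the line difference, so these shares do not settle the question either way.

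Each comparison of 2 treatments has 10 divisions of its 6 arrays, too few for a share under 0.05. By genes at an unadjusted p under 0.05, as many were reached in 2 divisions for Rhosin (560, highest other 670), 2 for JK136 (469, 627) and 10 for JK139 (218, 413) against DMSO. Between compounds it was 2 for JK136 and Rhosin (812, 841), 2 for JK139 and Rhosin (663, 802) and 3 for JK139 and JK136 (494, 528). By lists it was 2 for Rhosin (7, highest other 7), 7 for JK136 (3, 5) and 10 for JK139 (0, 3), and between compounds 3 (6, 9), 4 (4, 6) and 6 (4, 6). Among the 4 divisions that part the 2 arrays of every line, the highest other gene counts were 670, 447, 332, 775, 533 and 409 in the same order. With the 9 compound arrays fitted as 1 group against DMSO, 265 genes had an unadjusted p under 0.05, against 301 in the fit that keeps the compounds apart. Of 100 divisions, 86 reached the 265 genes (highest other 1010) and 79 reached the 1 list (highest other 9), and for the interaction 57 of 64 choices reached 244 genes (highest other 952). Chance is not excluded there, and divisions with several times the real count point to some other structure of the samples, which was not identified or tested.

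The rise of the immediate-early list with Rhosin could come from DMSO arrays with low values. Comparisons of Rhosin with JK136 and with JK139 leave these arrays out. The random lists used here draw genes independently, while this list's genes had an estimated correlation of 0.37. Percentiles among them therefore overstate how unusual a value is. In AGS the list medians were 0.69 and 0.50, both above 100% of random lists, so a low DMSO array does not explain the whole rise there. In SNU601 they were 0.12 and 0.09, above 99.5% and 99.3% of random lists. There the mean of JK136 and JK139 also lay above DMSO, by 0.05, higher than 99.55% of random lists. JK139 alone lay above DMSO by 0.11, about as much as Rhosin with 0.12. A low DMSO array in SNU601 therefore stays open as a part of the rise. In MKN1 Rhosin lay above JK139 by 0.16 and above JK136 by 0.02, higher than 68.5% of random lists, so a low DMSO array stays open there. Without the AGS Rhosin array the list had an adjusted p of 0.216, and without all AGS arrays of 0.0245 (over all alternatives 1.57e-11 to 0.436), so whether 1 array carries the result stays open.

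The interferon list stood high on 1 array, AGS with JK136. A DMSO array that stands apart does not explain the whole of it, since JK136 also exceeded JK139 in AGS, by a median of 0.53. That was above 100% of random lists, which draw genes independently, while this list's genes had an estimated correlation of 0.31. A scaling shift of the AGS JK136 array could not be tested by quantile normalization, which kept 107% of the median. RMA had already brought the arrays to 1 distribution, so a second pass could change little. The median over the genes tested was 6.17 on the AGS JK136 array and 6.22 on the AGS DMSO array. The array as a whole thus did not lie higher. A response limited to AGS could not be told from a property of the single culture: in SNU601 the list stood at 0.13, higher than in 99.5% of random lists, and AGS has no second JK136 array.

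Responses to 2 compounds in 1 line correlated, and sharing a DMSO array by itself produces correlation of this kind. The median covariance of 9 pairs was 0.0204, between 0.0135 and 0.0225, and simulations with a shared array and no effect gave 0.0211 to 0.0249. The simulated arrays, DMSO included, had the residual spread of the model, which also holds responses that differ between lines. The median covariance lay below every simulated value. The simulation therefore cannot show whether covariance beyond the shared array was present.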

How the results depend on the processing

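Most alternatives were chosen before the data were examined, and 4 were added after seeing them: leaving out each array for the lists, lists of at least 3 genes, leaving out each line for the size rule, and the alternatives for medians within AGS. Of the gene counts, 259 stayed within 1.5 times the reported count and 5 did not. For the treatment comparisons and the interaction the reported count was 0, so staying there means remaining at 0. All 5 that moved were among these. Of the values of named genes, 1288 kept their direction and side of the threshold. JK139, the mean of the compounds, the 2 other comparisons with JK139 and the interaction gave 0 genes under every alternative. The counts between lines lay between 4423 and 7109 for MKN1 and AGS, 3792 and 5248 for SNU601 and AGS, and 4234 and 6813 for SNU601 and MKN1.

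With an intensity trend and a robust prior, 1 gene passed for Rhosin (TIPARP, adjusted p 0.0477) and 2 for JK136 against Rhosin (TIPARP and GDA, smallest adjusted p 0.0463), while without a filter 1 passed for JK136 (MIR329-1, adjusted p 0.0218). At an adjusted p under 0.1, 1 gene passed for JK136 against Rhosin. Leaving out arrays or lines gave 0 to 3 genes there, with 3 without the MKN1 JK136 array. The cause was not tested.

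The 11 list calls against DMSO became 0 with an estimated correlation, 0 with fry, 7 after quantile normalization and 5 with no replicate block, and 2 to 17 when arrays or lines were left out (2 without AGS). The 14 calls between compounds became 0 with an estimated correlation, 0 with fry and 9 with no replicate block, and 2 to 17 when arrays or lines were left out (2 without AGS). The 19 calls between lines became 0 with an estimated correlation, 55 with fry, which tests a list without comparing it to other genes, and 10 with a filter at the 60th percentile, which leaves fewer genes. Over all called lists, 792 alternatives kept the call, 197 lost it and 5 reversed.

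The reversals all came from leaving out AGS or 1 of its arrays. The median of the replication genes with Rhosin ranged from −0.222 to −0.00372, and the direction of their test turned without the AGS Rhosin array, at a median of −0.010. The interferon-induced genes with JK136 ranged from −0.061 to 0.545, lowest without the AGS JK136 array. The replication genes in JK136 against Rhosin ranged from −0.050 to 0.226 (−0.050 without AGS, −0.024 without the AGS Rhosin array), and the interferon-induced genes in JK139 against JK136 from −0.429 to 0.059, highest without the AGS JK136 array. The cause was not tested beyond the weight of that array in a mean of 3 lines.

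The size rule gave 0 genes at 2-fold and 18 at 1.3-fold for Rhosin, 0 and 19 for JK136, and 6 at 1.3-fold for JK139. Without a filter it gave 7 for Rhosin and 4 for JK136, and with a filter at the 60th percentile 0 for JK136. With 1 line left out, so that 2 lines had to meet the rule, it gave 3 to 28 for Rhosin, 5 to 17 for JK136 and 1 to 5 for JK139. The median correlation of mean responses, 0.328, became 0.401 without a filter and 0.271 at the 60th percentile, and the cause was not tested.

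MT1X in SNU601 against AGS was called at an adjusted p of 0.0311 and lost its call after quantile normalization (0.0653) and without the treatment block (0.192), and CD68 in SNU601 against MKN1 lost its call without the block (0.0733). RHOC in MKN1 against AGS passed after quantile normalization (0.0406) and median centring (0.0480). Signal over background limits what can be seen of dim genes, and 5954 genes lay below the filter. Lists also lost members that had no gene symbol here, such as all 17 histone genes.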

Other observations

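No test was added for this part, and the adjusted p values come from comparisons chosen before the data were examined. MT2A and MT1X code for metallothioneins, small proteins that bind zinc and copper. MT2A stood at 8.42 ± 0.16 in MKN1, 6.48 ± 0.20 in AGS and 5.75 ± 0.34 in SNU601 (log2, SD, n = 4), and MT1X at 8.31 ± 0.13, 6.70 ± 0.31 and 6.94 ± 0.28. MT1X lay below DMSO in all 9 combinations of line and compound, with −0.76, −0.36 and −0.33 in AGS for Rhosin, JK136 and JK139, −0.32, −0.18 and −0.21 in MKN1 and −0.63, −0.11 and −0.29 in SNU601. MT2A lay higher with JK136 by 0.09 and had −0.27 with JK139. MT1F, another metallothionein gene, moved both ways, by 0.21 in AGS, −0.59 in MKN1 and 0.37 in SNU601 for the mean of the compounds. MT1E, the last of the 4 measured, had −0.10 with JK139, with 0.23 in AGS, −0.50 in MKN1 and −0.03 in SNU601. Of the 4 genes, 4 lay lower with Rhosin, 3 with JK136 and 3 with JK139. The 3 differences of a line share its DMSO array, and MT1X was not called for any compound (adjusted p 0.190 with Rhosin).

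CD68, a lysosomal glycoprotein used as a marker of macrophages, stood at 8.65 ± 0.24 in MKN1, 8.33 ± 0.20 in SNU601 and 6.14 ± 0.30 in AGS. ANKRD1, a target of YAP and SRF, stood at 9.32 ± 0.21 in AGS, 6.18 ± 0.79 in SNU601 and 5.54 ± 0.24 in MKN1, and with Rhosin it differed from DMSO by −1.82 in SNU601, −0.37 in MKN1 and 0.04 in AGS. DIAPH2 stood at 8.07 ± 0.12 in AGS, 7.85 ± 0.21 in MKN1 and 3.56 ± 0.37 in SNU601. With JK136, SREBF1 had a log2 fold change of −0.52 ± 0.12 and SCD of −0.38 ± 0.11, neither called (adjusted p 0.801 and 0.902). Of the 9 measured fatty acid synthesis genes, 4 passed adjusted over the list alone, 1 higher and 3 lower with JK136, and the list was not called by camera (adjusted p 0.175).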
